A study of Homo sapiens with 9 samples.

How the data were processed

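Natural killer (NK) cells, the innate lymphocytes that kill infected or transformed cells without prior sensitization, were isolated from human peripheral blood mononuclear cells and sorted by surface TIGIT, an inhibitory receptor, into 3 fractions called TIGIThigh, TIGITlow and TIGITnegative in the sample labels. The series text calls the middle fraction TIGITmedium; the name TIGITlow is kept here. Each fraction has 3 libraries of total RNA, 9 in all. Nothing in the labels says whether the replicates of a fraction came from separate donors, sorts or cultures, so the p-values measure only the spread between these libraries, which may be technical.

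The deposited file is a table of whole-number read counts per gene, not normalized, made by the authors. Per the series text, reads were trimmed with fastp 0.19.5 (minimum Phred score 30, minimum length 50 bp), aligned to GRCh38 with STAR 2.7.9a and counted per gene with featureCounts from Subread 1.6.1. The submitters' processing notes name the same tools and build. The series text also gives a minimum of 30 M paired-end reads of 250 bp per library, an RNA integrity number above 8.4, and edgeR 3.32.1 with a false discovery rate of at most 0.01 for differential expression. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Without them, reads cannot be told apart between a gene and its antisense or overlapping partner (SLC26A4 and SLC26A4-AS1, RDH10 and RDH10-AS1, KRT86 and KRT81), and counts of near-identical genes (XCL1 and XCL2, HSPA1A and HSPA1B, CCL3L3, CCL4L2, PRSS2, LILRA2, LILRP2, the KIR genes and PVRIG) are uncertain.

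The table holds 60616 Ensembl gene identifiers, all of which name a gene; 60419 matched a symbol. Positions are from GENCODE release 44 on GRCh38, the build of the counts. Total counts per library ran from 13.34 M to 18.16 M. All columns of the table belong to a labelled library. Counts of replicates were compared by a chi-square statistic over genes with at least 20 counts summed over the pair: it was 1.78 to 2.27 per gene between replicates when TIGITlow replicate 2 was left out, above the 1 that sampling noise alone gives, and 10.9 to 11.9 in the pairs with that library. No library was treated as a duplicate.

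Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr with the fraction as the group, which left 22575 genes, and libraries were scaled by TMM factors. A quasi-likelihood model with robust estimation was fitted to all 9 libraries with 1 mean per fraction and no block. Fractions were compared in pairs, all together (a test over the 3 fractions), and by the contrast of TIGITlow against the midpoint of the other 2. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.01, the submitters' own. Log2 fold changes are given with standard errors (SE), and levels as CPM after TMM, as mean ± SD of 3 libraries. The common biological coefficient of variation was 11.3%.

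Before the data were examined, 31 gene lists were fixed: 20 of NK cell biology, 7 of markers of other blood cells and 4 technical lists. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison, with a threshold of 0.05. Lists with under 3 tested members would not be tested, and no list fell under that. The adjusted p with an estimated correlation is printed beside it. Another tool, fry, asked whether the members of a list shift in the same direction on average, without reference to other genes. Members counted as higher or lower passed the gene test at 0.01 over all genes; counts adjusted over the list alone are given beside them.

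The rule for named genes was also fixed beforehand: TIGIT, TNFRSF9, CD226, CD96 and PVRIG; the 10 largest rises and 10 largest falls in TIGIThigh against TIGITnegative, and 5 each way in the other comparisons, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries compared; and up to 4 members of each list with the smallest p in TIGIThigh against TIGITnegative. HLA genes, Y-linked genes, antigen receptor variable segments and loci without a name were left out of the named genes, since the cells come from human donors or the reads cannot be assigned, and KIR genes are given as group means only. A gene that the rule would name is not reported here.

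The model and the list test were tested on counts simulated from the real means, library sizes and dispersions with 200 changed genes. The changed genes were drawn from those with a mean of at least 2 CPM, and the dispersions came from the fit to all libraries, TIGITlow replicate 2 included. For TIGIThigh against TIGITnegative, 43.3% of genes changed by 1.5-fold, 68.7% of those changed by 2-fold and 97.0% of those changed by 4-fold were called among 22119 genes, with 3 unchanged genes called. For TIGIThigh against TIGITlow the shares were 49.3%, 73.1% and 97.0% among 22114 genes, with 4 unchanged genes called. For TIGITlow against TIGITnegative they were 64.2%, 77.6% and 92.4% among 22134 genes, with 4 unchanged genes called. The simulation was run with an earlier seed too, and the numbers are those of the later seed.

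Alternatives planned beforehand were RLE and upper-quartile scaling, no low-count filter or a stricter one (10 counts in at least 6 libraries), DESeq2 1.42.0, limma-voom, a fit of only the 2 fractions compared, a replicate block, a threshold of 0.05, an estimated inter-gene correlation and leaving out each library in turn. An added alternative, without TIGITlow replicate 2 and TIGIThigh replicate 2 together, was chosen after seeing the number of genes detected per library.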

Results

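The data were gene counts from 9 total RNA libraries of human blood NK cells, 3 from each of the TIGIThigh, TIGITlow and TIGITnegative fractions. Total counts were 13.94, 15.45 and 14.15 M in the TIGIThigh libraries, 18.16, 13.34 and 14.53 M in the TIGITlow libraries and 14.46, 13.76 and 14.08 M in the TIGITnegative libraries. Genes with at least 1 count numbered 33615 to 36873 in 8 libraries and 39110 in TIGITlow replicate 2, which had the lowest total count. That library also lay apart from the other 8 on the first principal component of log2 CPM, which held 40.5% of the variance. On the second, with 22.8%, the TIGITnegative libraries lay at -34.6 to -32.5, TIGITlow replicates 1 and 3 at 1.13 and -5.28, the TIGIThigh libraries at 18.1 to 28.4 and TIGITlow replicate 2 at 36.3. Mitochondrially encoded genes took 5.08% to 5.27% of the counts in TIGIThigh, 4.37% to 4.77% in TIGITlow and 4.15% to 4.17% in TIGITnegative.

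**Figure D1:**
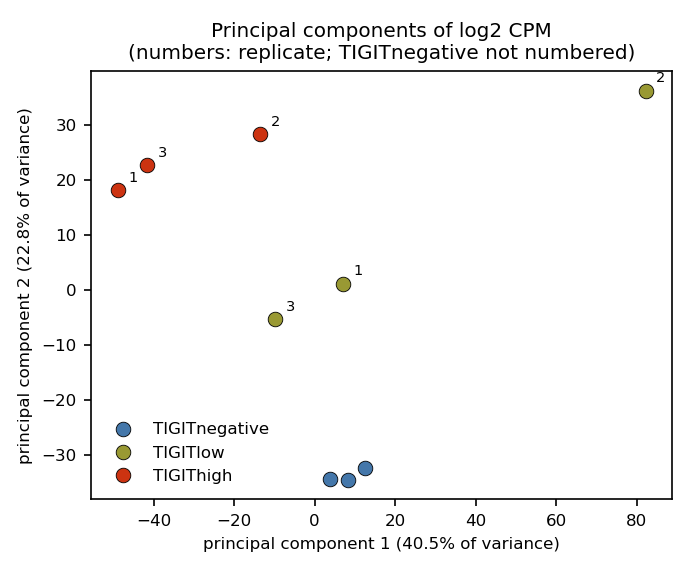
The first 2 principal components of log2 CPM over the tested genes (axes in component units, with the percent of variance), with 1 point per library, colored by fraction. TIGITlow replicate 2 lies at 82.2 on component 1, where the other 8 libraries lie between -49.0 and 12.6.

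The study's title concerns the link between TIGIT and 4-1BB, a costimulatory receptor encoded by TNFRSF9, so these genes were read first. TIGIT (ENSG00000181847, GRCh38 chromosome 3, 114276913 to 114310288) followed the sort, with 231 ± 8.41 CPM in TIGIThigh, 86.2 ± 5.49 in TIGITlow and 28.1 ± 2.69 in TIGITnegative (mean ± SD, n = 3 each, as for all levels here). TNFRSF9 (ENSG00000049249, chromosome 1, 7915871 to 7943165) had the same order, with 62.2 ± 2.43, 18.9 ± 1.16 and 9.37 ± 1.54 CPM. Both genes differed in each pair of fractions. TIGIT rose by 3.04 ± 0.08 (log2 ± SE) from TIGITnegative to TIGIThigh (adjusted p = 8.5e-13), and TNFRSF9 rose by 2.73 ± 0.10 (adjusted p = 5.8e-11). CD226, the activating receptor that shares ligands with TIGIT, had 306 ± 4.35, 343 ± 9.27 and 334 ± 14.3 CPM in TIGIThigh, TIGITlow and TIGITnegative, with an adjusted p of 0.16 for TIGIThigh against TIGITnegative. CD96, another receptor for these ligands, had 665 ± 19.1, 632 ± 28.1 and 634 ± 13.8 CPM (adjusted p = 0.50). PVRIG had 0 to 2 counts per library and was not tested; since the treatment of reads that match several genes is not given, its true level is open.

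**Figure D2:**
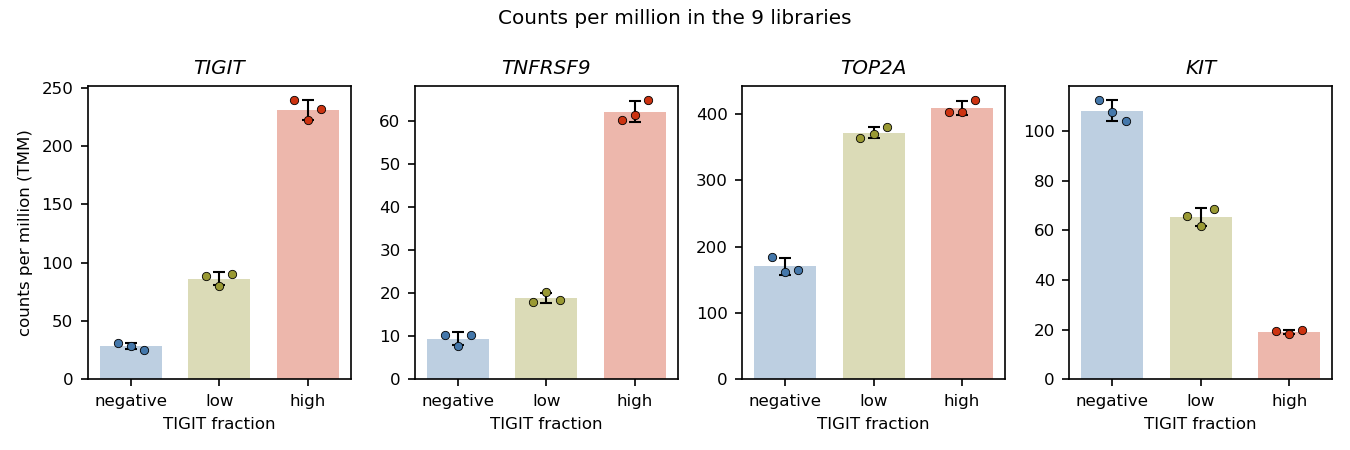
CPM (TMM scaling) of TIGIT, TNFRSF9, TOP2A and KIT by TIGIT fraction; bars are means, error bars SD and points the 3 libraries of each fraction. TIGIT and TNFRSF9 rise from negative to high, TOP2A is at 170 in negative against 372 in low and 409 in high, and KIT falls from 108 to 19.0.

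The widest comparison was TIGIThigh against TIGITnegative cells. TIGIThigh cells had higher levels of B3GAT1, which encodes the enzyme that makes the CD57 epitope of mature NK cells, at 9.40 ± 0.369 against 0.574 ± 0.0603 CPM (16.1-fold, adjusted p = 1.7e-08). They also had more of the inhibitory receptor CTLA4 (6.28-fold) and the transcription factors MYB (5.62-fold) and ZBED2 (7.15-fold). Genes lower in TIGIThigh included the metalloprotease MMP14, at 15.6 ± 2.40 against 107 ± 4.02 CPM (log2 fold change -2.78). All 29 tested cell cycle genes were higher, and 13 of 22 CD56bright NK cell markers were lower. In edgeR's quasi-likelihood test 3349 of 22575 genes changed at an adjusted p of at most 0.01, 1980 higher and 1369 lower, of which 309 rose and 278 fell by at least 2-fold.

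The other large rises in TIGIThigh were those of the anion transporter SLC26A4 (log2 fold change 3.07), the calcineurin regulator RCAN2 (2.66), and the antisense loci SLC26A4-AS1 (2.51) and RDH10-AS1 (2.49). Without a stated strand setting, the antisense loci cannot be told from SLC26A4 and RDH10. The other large falls were those of SPINK2 (-3.74), ASGR2 (-3.73), KRT81 (-3.51), PRSS2 (-3.34), LILRA2 (-3.27), KRT86 (-3.13), KCNK17 (-2.90) and SCARF1 (-2.83). KRT81 lies within the span of KRT86, and PRSS2 and LILRA2 have close relatives, so their reads may be shared.

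All 29 tested cell cycle genes rose in TIGIThigh, also when adjusted over the list alone, with a median log2 fold change of 0.99. RRM2, a subunit of the enzyme that makes deoxyribonucleotides, stood at 449 ± 6.82 against 185 ± 3.09 CPM, and TOP2A, the DNA topoisomerase of dividing cells, at 409 ± 10.6 against 170 ± 12.7 CPM. CCNA2 rose by 1.20 and BIRC5 by 1.16. The list lay above other genes in camera (adjusted p = 2.7e-27, adjusted p = 0.270 with an estimated correlation). Mitochondrially encoded genes moved the same way, with 11 of 13 higher and 2 not passing (13 higher when adjusted over the list alone), a median of 0.40 and an adjusted p of 4.6e-07 (adjusted p = 0.763 with an estimated correlation). MT-ND2 rose by 0.54 and MT-CYB by 0.45. The 11 mitochondrially encoded genes became 5 without TIGIThigh replicate 1 or 3 or TIGITnegative replicate 1 or 2, and 6 without TIGITnegative replicate 3.

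Markers of CD56bright NK cells, the less mature blood subset, were lower in TIGIThigh: 13 fell, 1 rose and 8 did not pass, the same counts as when adjusted over the list alone (median -0.62, adjusted p = 2.4e-07, adjusted p = 0.246 with an estimated correlation). KIT, the stem cell factor receptor, fell by 2.51, from 108 ± 4.25 to 19.0 ± 0.785 CPM, the adhesion receptor CD44 fell from 358 ± 9.62 to 151 ± 6.02 CPM and the chemokine XCL1, which may share reads with XCL2, fell by 1.68. The 1 rise was lost without TIGIThigh replicate 1 or 2 or any 1 TIGITnegative library. Beside them, 7 of 12 markers of innate lymphoid cells and progenitors fell and 5 did not pass (8 lower when adjusted over the list alone), with a median of -0.93 and an adjusted p of 7.9e-05 (adjusted p = 0.114 with an estimated correlation). They included SPINK2, KIT, which is on both lists, and TNFSF11, which fell by 2.47. B cell and plasma cell markers were also lower as a list, with 3 of 9 lower, 6 not passing, the same counts when adjusted over the list alone, a median of -1.18 and an adjusted p of 0.0067 (adjusted p = 0.773 with an estimated correlation). The 3 became 1 without TIGIThigh replicate 1 or 3 or TIGITnegative replicate 1 or 3. The most abundant of those named was BANK1, at 5.99 ± 1.36 against 13.8 ± 0.619 CPM.

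Markers of mature CD56dim NK cells went both ways, with 9 higher, 8 lower and 8 not passing (10 and 9 when adjusted over the list alone, adjusted p = 0.77). Their median was -0.08 while their mean was 0.12. ZEB2, a transcription factor of NK maturation, rose by 1.29 beside B3GAT1, while ZNF683 fell by 2.59 and FCRL6 by 1.71. Genes high in adaptive NK cells, which expand in cytomegalovirus carriers, were higher in 7, lower in 4 and not passing in 7, as when adjusted over the list alone (adjusted p = 0.23, the median of 0.05 turned to -0.02 with upper-quartile scaling). ZBTB38 rose by 0.97. B3GAT1, which rose, and ZNF683, which fell, are on this list as well as on that of mature CD56dim markers. The receptor TNFRSF18, which fell, is on this list and also on that of genes low in adaptive NK cells, so its fall counts in both. Of genes low in adaptive NK cells, 1 rose, 4 fell and 10 did not pass, also when adjusted over the list alone (adjusted p = 0.25). The 1 rise was lost without TIGIThigh replicate 1 or TIGITnegative replicate 2 or 3, and 2 rose without TIGITlow replicate 2. The adaptor FCER1G fell by 0.56 and the activating receptor NCR1 by 0.42.

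Among genes associated with T cell exhaustion, 10 rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone (median 0.32, adjusted p = 0.0012, adjusted p = 0.539 with an estimated correlation). The inhibitory receptor LAG3 stood at 178 ± 3.98 against 64.5 ± 1.95 CPM (log2 fold change 1.46), and the transcription factor MAF rose by 1.07. TNFRSF9 and CTLA4 are also on this list. Of other inhibitory receptors 5 rose, 2 fell and 9 did not pass, as when adjusted over the list alone (adjusted p = 0.23). CD300A fell by 1.40 and VSIR by 0.79. Of TNF receptor family costimulators and their adaptors, 6 rose, 6 fell and 7 did not pass (8 and 6 when adjusted over the list alone, adjusted p = 0.68). Their median was -0.01 and their mean 0.09, and the median turned to 0.01 with RLE scaling. The receptor TNFRSF18 fell by 1.02. Of NF-kB response genes 3 rose and 15 did not pass (4 when adjusted over the list alone, adjusted p = 0.21), with BIRC3 higher by 0.73 and RELB by 0.70. TIGIT and NECTIN3 were the genes of the TIGIT axis that rose, 2 of 8 also when adjusted over the list alone (adjusted p = 0.86, median -0.18, mean 0.14). NECTIN3 rose by 0.62, but did not pass without TIGIThigh replicate 3 (0.57) or without TIGITnegative replicate 1 (0.52). NF-kB response genes had 8 higher and 2 lower without TIGITlow replicate 2, exhaustion-associated genes 3 lower, other inhibitory receptors 4 lower and TIGIT axis genes 2 lower.

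Activating receptors and adaptors were higher in 3, lower in 6 and not passing in 7 (3 and 7 when adjusted over the list alone, adjusted p = 0.23). FCGR3A, which encodes the CD16 receptor for antibody-coated cells, rose by 0.84 and SLAMF6 by 0.58, and NCR2 fell by 0.90. Of killer immunoglobulin-like receptor genes, whose reads may be shared, 1 of 4 fell and 3 did not pass (2 lower when adjusted over the list alone, adjusted p = 0.12). Of cytotoxic granule and death ligand genes, 5 rose, 6 fell and 7 did not pass (5 and 9 when adjusted over the list alone, adjusted p = 0.48). The lytic protein gene GNLY had 8098 ± 253 against 13297 ± 155 CPM, while RAB27A and STX11, which act in granule release, rose by 0.73 and 0.79. Of cytokines and chemokines, 4 rose, 6 fell and 8 did not pass (5 and 6 when adjusted over the list alone, adjusted p = 0.79), with CCL4L2 and CCL3L3, members of near-identical gene families, higher by 1.40 and 1.28. Of cytokine receptors and signalling genes, 4 rose, 5 fell and 18 did not pass (5 and 9 when adjusted over the list alone, adjusted p = 0.68). IL2RA, the high-affinity interleukin-2 receptor chain, stood at 272 ± 12.8 against 113 ± 5.36 CPM, SOCS2 rose by 1.38 and IL18R1 fell by 0.95. Cytokine receptors had 7 higher and 9 lower without TIGITlow replicate 2, cytokines and chemokines 7 higher and killer immunoglobulin-like receptors 2 lower. Lower cytotoxic granule genes numbered 3 without any 1 TIGIThigh or TIGITnegative library.

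Glycolysis genes were lower in TIGIThigh, with 11 lower, 1 higher and 8 not passing, also when adjusted over the list alone (median -0.42, adjusted p = 2.5e-05, adjusted p = 0.775 with an estimated correlation). The glucose transporter SLC2A3 fell by 0.95 and hexokinase HK2 by 0.83, whereas the lactate and pyruvate transporter SLC16A1 rose by 1.64. Immediate early genes, which respond within minutes to handling and stimulation, had 10 lower, 2 higher and 13 not passing, as when adjusted over the list alone (median -0.20, adjusted p = 0.0018, adjusted p = 0.872 with an estimated correlation). EGR1 fell by 1.17 and ATF3 rose by 1.04, and 17 members were lower and 4 higher without TIGITlow replicate 2. Of residency, adhesion and homing genes, 5 rose, 12 fell and 12 did not pass (6 and 13 when adjusted over the list alone, median -0.23, adjusted p = 0.014, adjusted p = 0.909 with an estimated correlation). The integrin ITGAX had 738 ± 22.7 against 2176 ± 56.0 CPM, ITGA5 fell by 1.06, and the chemokine receptor CXCR4 had 109 ± 2.31 against 33.5 ± 0.177 CPM.

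Of lymphocyte transcription factors 13 rose, 11 fell and 18 did not pass (15 and 11 when adjusted over the list alone, adjusted p = 0.75), and their median of 0.01 turned to -0.06 with upper-quartile scaling. IKZF3 rose by 1.57. Interferon-stimulated genes had 8 higher, 4 lower and 21 not passing, as when adjusted over the list alone (adjusted p = 0.34), with EPSTI1 higher by 0.90 and IFITM3 lower by a log2 fold change of -0.98. Heat shock and protein stress genes had 5 higher, 3 lower and 7 not passing, also when adjusted over the list alone (adjusted p = 0.48). Of nuclear-encoded oxidative phosphorylation genes 2 of 33 rose, and of ribosomal protein genes 2 of 33, with 0 on either list when adjusted over the list alone (adjusted p = 0.48 and 0.34). The oxidative phosphorylation median of 0.01 turned to -0.06 with upper-quartile scaling. T cell markers had 4 higher, 3 lower and 9 not passing (6 and 3 when adjusted over the list alone, adjusted p = 0.21), with SLC4A10 higher by 1.06 and CD6 by 1.99. CD6, CD5, CD3D, CD3E and CD3G are also on the list of genes high in adaptive NK cells, and LEF1 on that of CD56bright markers. These members therefore do not by themselves mark T cells. Of monocyte and neutrophil markers 1 of 9 rose (adjusted p = 0.42), and of dendritic cell markers 1 of 5, BATF3, a factor also used by lymphocytes, by 1.48 (adjusted p = 0.99, median -0.25, mean 0.01). Both counts were the same when adjusted over the list alone. None of 7 platelet markers (adjusted p = 0.44) and none of 3 erythroid markers (adjusted p = 0.56) passed in edgeR with all libraries, either way of adjusting, with 0 on either list at an unadjusted p under 0.05, in DESeq2 and in limma-voom. Ribosomal protein genes had 13 higher and 4 lower without TIGITlow replicate 2, oxidative phosphorylation genes 5 higher and 2 lower, and monocyte markers 2 lower. Higher ribosomal protein genes numbered 4 without TIGITlow replicate 3. The calls on oxidative phosphorylation genes were lost without any 1 TIGIThigh or TIGITnegative library, those on ribosomal protein genes without any of these but TIGIThigh replicate 2, and the monocyte call without TIGIThigh replicate 1 or 3 or TIGITnegative replicate 1 or 2. Higher interferon-stimulated genes numbered 5 without TIGIThigh replicate 3 or TIGITnegative replicate 3 and 4 without TIGITnegative replicate 2. Higher heat shock genes numbered 3 without TIGIThigh replicate 1 or 3 or any 1 TIGITnegative library, and lower T cell markers 1 without TIGIThigh replicate 2 or 3 or TIGITnegative replicate 1.

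**Figure D3:**
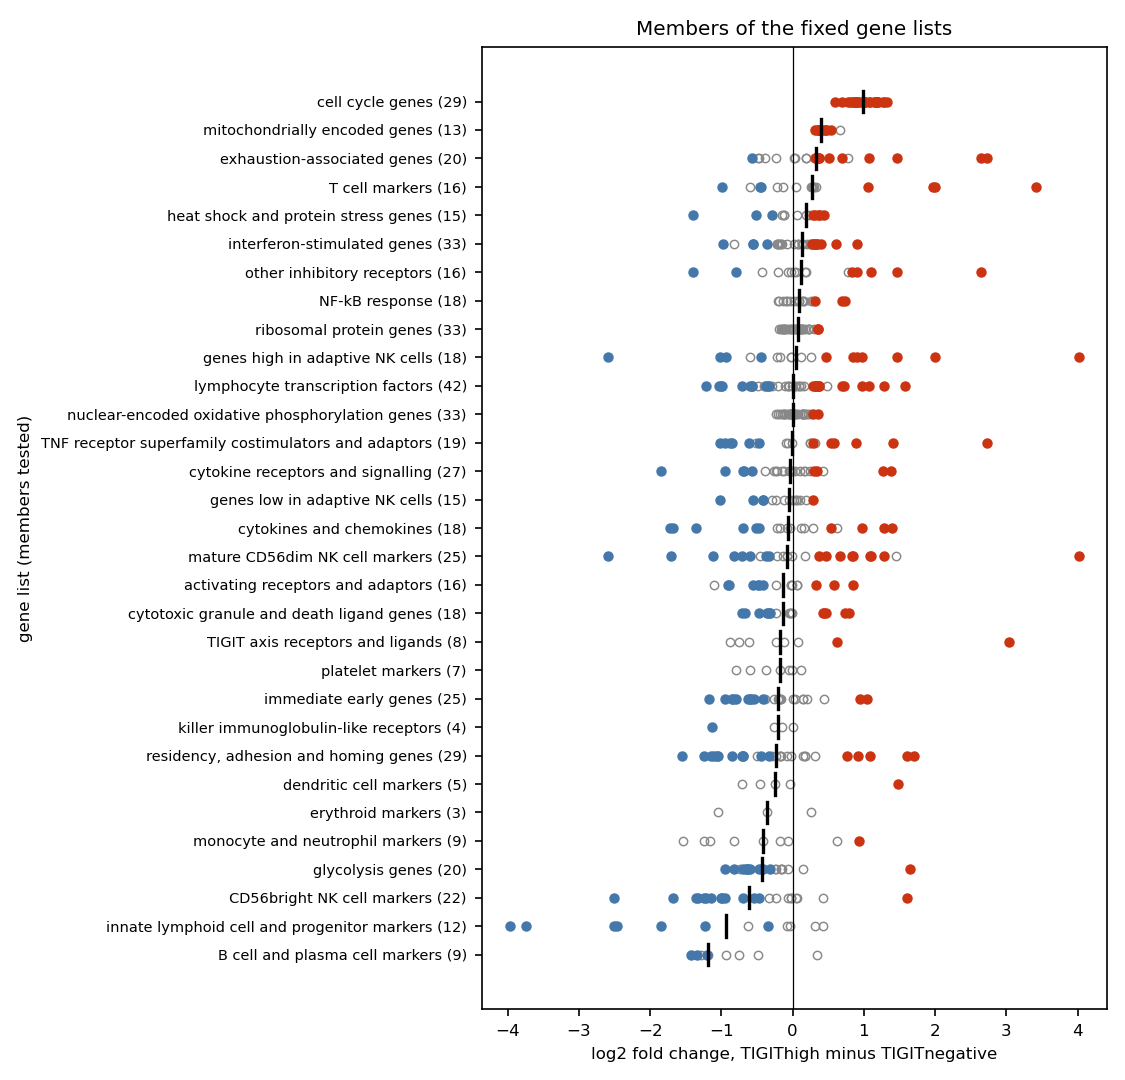
Log2 fold change, TIGIThigh minus TIGITnegative, of every tested member of the 31 gene lists (1 line per list, with the number tested); filled points passed an adjusted p of 0.01 (red higher, blue lower), open points did not, and black bars are medians. All 29 cell cycle genes lie above 0, and with upper-quartile scaling the medians of adaptive NK genes, transcription factors and oxidative phosphorylation, near 0 here, turn negative.

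All 3349 changed genes had no overlap between the 3 TIGIThigh and 3 TIGITnegative libraries, as did 43.3% of all tested genes, where chance gives 10%. The share of higher genes was 59.1% with TMM and 45.0% (1806 higher, 2206 lower) with upper-quartile factors, which shift the median log2 fold change of all genes to -0.10 from -0.04. Without TIGITlow replicate 2, which is in neither fraction but enters the common spread, 5968 genes changed, among them 3348 of the 3349. With an estimated correlation none of the 9 lists called in this comparison, nor any called in the others, remained past 0.05 in camera. At an unadjusted p under 0.05 camera with an estimated correlation had 3, 2 and 3 of 31 lists for TIGIThigh against TIGITnegative, TIGIThigh against TIGITlow and TIGITlow against TIGITnegative. At an adjusted p of at most 0.05 fry called 15, 12 and 6.

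TIGIThigh cells were next compared with TIGITlow cells. TIGIT was 2.68-fold higher (log2 fold change 1.42 ± 0.07, adjusted p = 3.8e-09) and TNFRSF9 3.29-fold higher (1.72 ± 0.09, adjusted p = 6.9e-09), while CD226 (adjusted p = 0.08) and CD96 (adjusted p = 0.42) did not pass. B3GAT1 rose by 2.14, ZBED2 by 1.79, the noncoding LINC02363 by 1.80 and the retinol dehydrogenase RDH10 by 1.66. The large falls included those of ASGR2 (log2 fold change -2.84), KRT81 (-2.70), SPINK2 (-2.49) and the cytokine IL26 (-2.48). In all, 1003 genes changed, 626 higher and 377 lower, with 47 and 100 of them by at least 2-fold.

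Of cell cycle genes 13 rose and 16 did not pass (19 higher when adjusted over the list alone, median 0.34, adjusted p = 1e-11, adjusted p = 0.50 with an estimated correlation). The 13 became 3, 8 and 4 without TIGIThigh replicates 1, 2 and 3, 7 and 20 without TIGITlow replicates 1 and 3, and 7 without TIGITnegative replicate 2. TOP2A, at 409 ± 10.6 against 372 ± 8.49 CPM, did not pass (adjusted p = 0.16). Mitochondrially encoded genes had 1 higher and 12 not passing (9 higher when adjusted over the list alone, adjusted p = 2.2e-06, adjusted p = 0.50 with an estimated correlation). They had 10 higher without TIGITlow replicate 2 and 7 without TIGITlow replicate 3, and the 1 call was lost without any 1 of the other 7 libraries. CD56bright markers had 10 lower and 12 not passing (12 lower when adjusted over the list alone, adjusted p = 2.2e-06, adjusted p = 0.358 with an estimated correlation), with KIT lower by a log2 fold change of -1.78 and CD44 of -0.91. Innate lymphoid markers had 5 lower, 1 higher and 6 not passing, as when adjusted over the list alone (adjusted p = 0.00020, adjusted p = 0.152 with an estimated correlation). Of exhaustion-associated genes 7 rose, 1 fell and 12 did not pass (9 and 1 when adjusted over the list alone, adjusted p = 0.00029, adjusted p = 0.425 with an estimated correlation), and LAG3 rose by 1.08, CTLA4 by 1.57 and MAF by 1.01. TNF receptor family genes had 6 higher, 1 lower and 12 not passing (6 and 3 when adjusted over the list alone, adjusted p = 0.025, adjusted p = 0.50 with an estimated correlation), and NF-kB response genes 3 higher, among them RELB (0.53), and 15 not passing, also when adjusted over the list alone (adjusted p = 0.00036, adjusted p = 0.50 with an estimated correlation). Genes high in adaptive NK cells had 7 higher, 2 lower and 9 not passing (8 and 2 when adjusted over the list alone, adjusted p = 0.0072, adjusted p = 0.50 with an estimated correlation). Among residency genes CXCR4 rose by 0.89 and ITGAX fell by 0.77, in a list with 4 higher, 10 lower and 15 not passing, as when adjusted over the list alone (adjusted p = 0.11). Without TIGITlow replicate 2, the lists of TNF receptor family genes (adjusted p = 0.185) and of genes high in adaptive NK cells (adjusted p = 0.077) did not pass, while the lists of residency (adjusted p = 0.00069), glycolysis (adjusted p = 8.8e-06, 0.080 with all libraries) and immediate early genes (adjusted p = 0.040, 0.92 with all libraries) did. With an estimated correlation, 0 lists passed without TIGITlow replicate 2. With the preset correlation, glycolysis genes also passed without TIGIThigh replicate 1 (adjusted p = 0.048). Other inhibitory receptors (adjusted p = 0.053 with all libraries) passed without replicate 2 or 3 of TIGIThigh or TIGITnegative, or 1 or 3 of TIGITlow. Cytotoxic granule genes (0.073) passed without TIGIThigh replicate 2 or TIGITlow replicate 1 or 3, and cytokines and chemokines (0.10) without TIGITlow replicate 3. Higher TNF receptor family genes numbered 2 without any 1 TIGIThigh library, and higher NF-kB response genes 5 without TIGITlow replicate 3. Lower members without TIGITlow replicate 2 were 5 TNF receptor family genes, 4 genes high in adaptive NK cells, 11 glycolysis genes and 8 immediate early genes. The 1 lower TNF receptor family gene was lost without any 1 of the other 8 libraries, the 1 lower exhaustion-associated gene without TIGIThigh replicate 1 or 3, and the 1 higher innate lymphoid marker without any 1 TIGIThigh or TIGITnegative library.

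Camera also called other lists in TIGIThigh against TIGITlow. Most members did not pass in each of them but the killer immunoglobulin-like receptor genes. Ribosomal protein genes had 1 of 33 past the threshold (0 when adjusted over the list alone, adjusted p = 3.3e-07, adjusted p = 0.566 with an estimated correlation), and oxidative phosphorylation genes had 0 of 33 in edgeR by either adjustment (13 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom, adjusted p = 7.5e-05, adjusted p = 0.581 with an estimated correlation). Interferon-stimulated genes had 2 higher and 1 lower of 33 (4 and 1 when adjusted over the list alone, adjusted p = 0.025, adjusted p = 0.632 with an estimated correlation), with EPSTI1 higher by 0.54. Heat shock genes had 2 of 15 higher (4 higher and 1 lower when adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.612 with an estimated correlation). T cell markers had 4 of 16 higher (6 higher and 1 lower when adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.425 with an estimated correlation). Among them CD6, which is also on the list of genes high in adaptive NK cells, rose by 1.52. B cell markers had 1 of 9 lower (2 when adjusted over the list alone, adjusted p = 0.00029, adjusted p = 0.50 with an estimated correlation). Killer immunoglobulin-like receptor genes had 2 of 4 lower (3 when adjusted over the list alone, adjusted p = 0.010, adjusted p = 0.50 with an estimated correlation). Interferon-stimulated genes did not pass without TIGITlow replicate 2 (adjusted p = 0.245) or TIGIThigh replicate 1 (adjusted p = 0.065), heat shock genes without TIGITlow replicate 2 (adjusted p = 0.185), or killer immunoglobulin-like receptor genes without TIGITlow replicate 3 (adjusted p = 0.053). Ribosomal protein genes had 12 higher without TIGITlow replicate 2, oxidative phosphorylation genes 3 higher, heat shock genes 4 higher and 2 lower, interferon-stimulated genes 3 lower and T cell markers 2 lower. Without TIGITlow replicate 3, ribosomal protein genes had 9 higher, oxidative phosphorylation and heat shock genes 4 higher each and B cell markers 2 lower. The ribosomal call was lost without any 1 of the other 7 libraries, and the 1 lower interferon-stimulated gene without any 1 library but TIGITlow replicate 2. Higher interferon-stimulated genes numbered 1 without TIGIThigh replicate 1 or 3, higher heat shock genes 1 without TIGIThigh replicate 3, and lower killer immunoglobulin-like receptors 1 without any 1 TIGIThigh library. Beside these lists, ribosomal protein genes took 2.39% of the counts in TIGITlow replicate 2, against 2.77% and 2.80% in the other TIGITlow libraries and 2.85% to 2.91% in TIGIThigh.

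The share of higher genes in TIGIThigh against TIGITlow was 62.4% with TMM and 41.7% (562 higher, 787 lower) with upper-quartile factors, which shift the median of all genes to -0.11 from -0.03. Lower genes also outnumbered higher ones without TIGIThigh replicate 1 (199 higher, 208 lower) or 3 (197 and 208) and in a fit of only these 2 fractions (157 and 164). All 1003 genes had no overlap between the libraries compared, as did 31.4% of those tested, against 10% by chance. The count was 2099 without TIGITlow replicate 2, 1532 without TIGITlow replicate 3, 407, 566 and 405 without TIGIThigh replicates 1, 2 and 3, and 651 without TIGITnegative replicate 2. With a replicate block it was 1660.

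TIGITlow cells were compared with TIGITnegative cells to see what already differed at a lower level of the receptor. TIGIT was 3.06-fold higher (log2 fold change 1.62 ± 0.08, adjusted p = 1.6e-08) and TNFRSF9 2.01-fold higher (1.01 ± 0.11, adjusted p = 1.6e-05), while CD226 (adjusted p = 0.71) and CD96 (adjusted p = 0.97) did not pass. Cell cycle genes made the clearest group, with 26 of 29 higher and 3 not passing (28 higher when adjusted over the list alone, median 0.73, adjusted p = 9.2e-26, adjusted p = 0.302 with an estimated correlation). TOP2A had 372 ± 8.49 against 170 ± 12.7 CPM and RRM2 358 ± 14.7 against 185 ± 3.09 CPM. SLC26A4 rose by 1.49, MYB by 1.28, the noncoding CRNDE by 1.22 and ZEB2 by 0.68. SPINK2 fell from 9.53 ± 1.46 to 3.98 ± 0.475 CPM, but did not pass without TIGITnegative replicate 1, 2 or 3 (-1.31, -1.33 and -1.12). The largest falls after it were those of LILRP2 (-1.21), whose reads may be shared with its family, MXRA8 (-1.10), the Notch ligand DLL1 (-1.10) and SCARF1 (-1.09). In all, 1378 genes changed, 651 higher and 727 lower, with 37 and 9 of them by at least 2-fold.

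CD56bright markers had 8 lower and 14 not passing (11 lower when adjusted over the list alone, adjusted p = 6.9e-06, adjusted p = 0.302 with an estimated correlation), with KIT at 65.4 ± 3.46 against 108 ± 4.25 CPM and XCL1 lower by a log2 fold change of -0.72. Innate lymphoid markers had 4 of 12 lower, also when adjusted over the list alone (adjusted p = 0.0032, adjusted p = 0.302 with an estimated correlation). Glycolysis genes had 6 lower, 1 higher and 13 not passing (15 and 1 when adjusted over the list alone, adjusted p = 6.9e-06, adjusted p = 0.824 with an estimated correlation), and SLC16A1 rose by 0.79. Immediate early genes had 9 lower, 1 higher and 15 not passing (11 and 1 when adjusted over the list alone, adjusted p = 1.6e-06, adjusted p = 0.824 with an estimated correlation), with EGR1 lower by a log2 fold change of -0.59 and BTG2 of -0.55. Cytokines and chemokines had 6 of 18 lower, as when adjusted over the list alone (adjusted p = 0.0087, adjusted p = 0.824 with an estimated correlation). Residency genes had 6 lower and 3 higher of 29 (11 and 5 when adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.824 with an estimated correlation), with ITGAX lower by a log2 fold change of -0.78 and CXCR4 higher by 0.82. Cytotoxic granule genes had 3 lower and 1 higher of 18 (8 and 2 when adjusted over the list alone, adjusted p = 0.0021, adjusted p = 0.824 with an estimated correlation), activating receptors 3 lower and 1 higher of 16 (7 and 2 when adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.824 with an estimated correlation), and genes low in adaptive NK cells 1 of 15 lower (4 lower and 1 higher when adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.824 with an estimated correlation). Without TIGITlow replicate 2 the last 5 of these lists did not pass: cytokines and chemokines (adjusted p = 0.18), residency (adjusted p = 0.33), cytotoxic granule (adjusted p = 0.12), activating receptor (adjusted p = 0.28) and low in adaptive NK cells (adjusted p = 0.26). The residency list also did not pass without TIGITnegative replicate 1 (adjusted p = 0.059). Without 1 TIGITnegative library the lower genes numbered at most 2 for glycolysis, 2 for innate lymphoid markers, 3 for cytokines and chemokines and 1 each for cytotoxic granule genes and activating receptors, and without TIGITnegative replicate 3 they numbered 5 for CD56bright markers and 5 for immediate early genes, the latter also without TIGITnegative replicate 2. Lower glycolysis genes numbered 3 without TIGIThigh replicate 3 and 13 without TIGITlow replicate 2. Lower cytotoxic granule genes numbered 1 without any 1 TIGIThigh library and 8 without TIGITlow replicate 2 or 3. Lower activating receptors numbered 1 without TIGIThigh replicate 3 and 5 without TIGITlow replicate 2. Genes low in adaptive NK cells numbered 2, 5 and 3 lower without TIGITlow replicates 1, 2 and 3, and 2 higher without TIGITlow replicate 2. The 1 higher activating receptor was lost without any 1 TIGITnegative library, and the 1 higher cytotoxic granule gene without these or TIGITlow replicate 1 or 3; each numbered 2 without TIGITlow replicate 2, as did higher immediate early genes and higher cytokines and chemokines. Residency genes numbered 5 higher without TIGITlow replicate 2 and 11 lower without TIGITlow replicate 3.

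Ribosomal protein genes were lower as a list in TIGITlow than in TIGITnegative with 0 of 33 members past the threshold in edgeR by either adjustment (13 at an unadjusted p under 0.05, 3 in DESeq2 and 0 in limma-voom, median -0.15, adjusted p = 2.3e-05, adjusted p = 0.824 with an estimated correlation), and oxidative phosphorylation genes with 2 of 33 lower, also when adjusted over the list alone (adjusted p = 0.0014, adjusted p = 0.824 with an estimated correlation). Ribosomal protein genes had 4 lower without TIGITlow replicate 2 or 3. The oxidative phosphorylation calls were lost without any 1 TIGIThigh or TIGITnegative library, and numbered 1 without TIGITlow replicate 1. Neither list passed without TIGITlow replicate 2 (adjusted p = 0.28 and 0.73), while exhaustion-associated genes (adjusted p = 0.037) and mitochondrially encoded genes (adjusted p = 2.7e-05) did. Camera called 12 lists with all libraries and 7 without that library, but 0 in either fit with an estimated correlation. The balance of higher and lower genes turned with the setting: 1460 were higher and 1107 lower without TIGITlow replicate 2, 601 and 1012 without TIGITlow replicate 3, 932 and 1251 with upper-quartile factors, and 433 and 221 in a fit of only these 2 fractions. Without a TIGIThigh or a TIGITnegative library, higher genes made up 56.3% to 65.5%, against 47.2% with all libraries. The count of changed genes was 2567 without TIGITlow replicate 2 and 748, 592 and 537 without TIGITnegative replicates 1, 2 and 3. All 1378 genes had no overlap between the libraries compared, as did 29.2% of those tested, against 10% by chance.

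**Figure D4:**
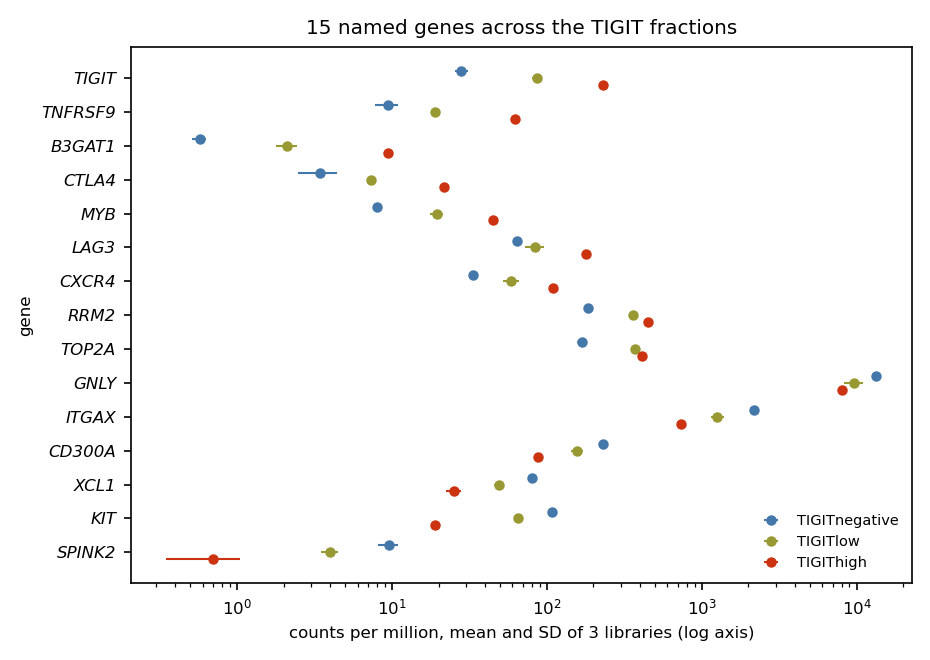
Mean CPM of 15 named genes in each fraction on a log axis, with SD bars (3 libraries per fraction). TIGITlow lies between the other fractions for each gene shown, as for TIGIT at 86.2 between 28.1 and 231. The 15 were picked from the named genes for display. Among all genes tested, 23 of those off the midpoint had a TIGITlow mean outside the range of the other means.

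Across the 3 fractions 3236 genes differed. Of the 587 genes that changed by at least 2-fold between TIGIThigh and TIGITnegative, 571 (97.3%) had their TIGITlow mean between the other means, as TIGIT, TNFRSF9 and KIT did. The TIGITlow mean lay at a median of 57.6% of the log2 distance from TIGITnegative to TIGIThigh for the genes that rose and 33.1% for those that fell. On the log2 scale, TIGITlow lay off the midpoint of the other fractions for 87 genes, above it for 71 and below it for 16. Of the 87, 23 had a TIGITlow mean outside the range of the other means. The plain average of 2 unequal levels lies above their midpoint on this scale, whether a gene rises or falls. The split of 71 and 16 and the shares of 57.6% and 33.1% therefore do not by themselves set TIGITlow apart from such an average. The count across fractions was 5871 without TIGITlow replicate 2, 2066 without TIGIThigh replicate 3 and 2024 and 1977 without TIGITnegative replicates 2 and 3. The count off the midpoint was 552 without TIGITlow replicate 2, 47 without TIGITlow replicate 1, 41, 42 and 43 without TIGIThigh replicates 1, 2 and 3, and 34, 25 and 31 without TIGITnegative replicates 1, 2 and 3.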

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

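The alternative without TIGITlow replicate 2 and TIGIThigh replicate 2 together was chosen after the data were seen; all others were planned. None of the 360 gene results (a gene in a comparison) or 93 list results reversed. Of 228 called gene results, 169 were called under every alternative and 176 in every fit without 1 library; 154 direction changes occurred in results called in neither fit. The log2 fold changes of TIGIT and TNFRSF9 kept their direction and call in every fit: without 1 library they ranged from 2.97 to 3.11 and 2.60 to 2.80 for TIGIThigh against TIGITnegative, 1.36 to 1.46 and 1.67 to 1.76 for TIGIThigh against TIGITlow, and 1.54 to 1.68 and 0.88 to 1.08 for TIGITlow against TIGITnegative. For TIGIThigh against TIGITnegative, TIGIThigh against TIGITlow and TIGITlow against TIGITnegative, the changed genes ranged from 2274 to 5968, 405 to 2099 and 537 to 2567 without 1 library, and lists from 9 to 9, 14 to 17 and 7 to 15. Genes differing among the 3 fractions ranged from 1977 to 5871, and genes off the midpoint from 25 to 552. Fitting only the 2 fractions compared called 5913, 321 and 654 genes in these comparisons; each such fit estimates the spread from its own 6 libraries, and those of the last 2 include TIGITlow replicate 2. A threshold of 0.05 called 5025, 2639 and 2808 genes, 5591 among the 3 fractions and 543 off the midpoint. Without both libraries 5995, 2486 and 2961 genes changed, 6054 differed among the fractions, 796 were off the midpoint, and 6 lists were called for TIGITlow against TIGITnegative. Upper-quartile scaling called 2183 genes for TIGITlow against TIGITnegative and 270 off the midpoint, and RLE scaling 45 off the midpoint. Without a low-count filter 1739 genes changed for TIGIThigh against TIGITlow and 798 were off the midpoint, where the stricter filter gave 132 and DESeq2 326. With an estimated inter-gene correlation 0, 0 and 0 lists were called by camera (3, 2 and 3 at an unadjusted p under 0.05), against 9, 15 and 12 with the preset one. The counts were likewise 0, 0 and 0 with the replicate block added. At an adjusted p of at most 0.05 fry called 15, 12 and 6. The replicate block gave 1660 genes for TIGIThigh against TIGITlow and 319 off the midpoint, 3829 and 1976 for TIGIThigh and TIGITlow against TIGITnegative, and changed no list call with the preset correlation. Replicate numbers were not treated as pairs: deviations of same-number libraries from their fraction means correlated above 0.1 in 4 of 9 pairs (-0.017 to 0.395). These included every pair of TIGIThigh with TIGITlow (0.168, 0.395 and 0.117 for replicates 1, 2 and 3), though TIGIThigh replicate 1 correlated more with TIGITlow replicate 3 (0.237). In all, 5 of 9 libraries correlated best with their own number. Where not stated, the cause was not tested. At this depth 43.3% of simulated 1.5-fold changes were called for TIGIThigh against TIGITnegative, so smaller changes among genes not passing are not excluded.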

Other observations

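The tests of sequencing depth, of larger cells in a brighter gate and of innate lymphoid cells below were chosen after the results were seen. The genes in this paragraph were also chosen after their values were seen. No list of their pathways was tested. PHGDH, the first enzyme of serine synthesis, was higher in TIGIThigh than in TIGITnegative, with 176 ± 4.07 against 80.2 ± 1.95 CPM (log2 fold change 1.13, adjusted p = 4.4e-08), PSAT1 rose by 1.33, MTHFD2 by 0.79 and SHMT2 by 0.51. TIGITlow stood between, at 118 ± 16.3 CPM for PHGDH. The cytokine LIF was lower in TIGIThigh, at 13.4 ± 0.949 CPM against 54.7 ± 8.69 in TIGITlow and 79.1 ± 2.11 in TIGITnegative. CSF1, a growth factor of macrophages, had 288 ± 9.90 CPM in TIGIThigh against 148 ± 17.7 in TIGITlow and 151 ± 3.68 in TIGITnegative.

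For 4 further genes, also chosen after their values were seen, TIGITlow lay above the midpoint of the other fractions. KNL1, a kinetochore scaffold, had 127 ± 6.60, 127 ± 5.58 and 63.7 ± 1.34 CPM in TIGIThigh, TIGITlow and TIGITnegative. CENPE had 113 ± 6.81, 115 ± 9.37 and 57.6 ± 1.66 CPM, and KIF14 and BRCA2 were likewise above the midpoint in TIGITlow, by 0.42 and 0.49 on the log2 scale. Their near-equal levels in TIGIThigh and TIGITlow do not stand for the cell cycle list, of which 13 of 29 genes were higher in TIGIThigh (median 0.34). That list did rise more from TIGITnegative to TIGITlow, with a median of 0.73. Of the 71 genes above the midpoint in TIGITlow, 43 were higher in TIGIThigh than in TIGITnegative and 28 lower.

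TIGITlow replicate 2 stood apart from the other 8 libraries, with 39110 genes detected. Sequencing depth is argued against, since that library had the lowest total count, 13.34 M, and the most genes; the lead of 3461 genes with every library thinned to that total follows from this. Another blood cell type stays open: over 49 markers of 6 types the excess over its fellow TIGITlow libraries was 0.22 on the log2 scale, -0.0611 from the median of expression-matched lists (0.28), but a pooled median would hide a single type. Taken by type, the highest excess over matched lists was 0.326, for 5 dendritic cell markers (0.30, where the central 95% of matched lists reached 0.45). Olfactory receptor genes, which lymphocytes do not use, had 2.28 times the CPM of the mean of the other 8 libraries (83.9 against 27.7 to 41.7), and near-silent protein-coding genes, lncRNAs and pseudogenes, chosen by their level in the other 8, were 2.20 to 2.76 times higher. Such a choice gives some excess by itself: in each other library, with genes chosen from the remaining 7, it was at most 1.51 times. A candidate explanation is genomic DNA counted in that library, and no biological explanation was tested for it.

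Cell cycle genes were higher in TIGIThigh and TIGITlow than in TIGITnegative, but were expressed in all 3 fractions. MKI67, chosen after its values were seen, had 838 ± 9.89, 794 ± 68.2 and 436 ± 9.57 CPM in TIGIThigh, TIGITlow and TIGITnegative. TOP2A, the topoisomerase of dividing cells, had 161 to 185 CPM in the TIGITnegative libraries, where both genes were lowest. Such levels of both genes in every fraction argue against fractions of resting NK cells alone. The marker lists of NK cell subsets were therefore not shown to be read in resting blood cells. GC content and transcript length are argued against, since the list's median of 0.99 lay 0.944 above the median of lists matched on both and on expression, and above the highest of 10000 such lists (0.26). Larger cells in a brighter gate cannot be told apart from this pattern: the difference of TIGIT itself, 3.04 on the log2 scale, follows from the sort, so it decides nothing about cell size. A larger share of cycling cells among TIGIT-bearing NK cells is the biological hypothesis and was not tested on single cells.

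KIT, SPINK2 and TNFSF11 were lower in TIGIThigh than in TIGITnegative. Innate lymphoid cells of another type in the TIGITnegative sort are a possible explanation, to which an NK cell gate would set a limit. Of the list of innate lymphoid markers, 8 further tested members had a median of -0.213 (quartiles -0.78 and 0.05), but this leaves out the members that fell most and excludes nothing. IL7R, which those cells carry, stood at 1.84 ± 0.258 CPM in TIGITnegative and 2.47 ± 0.231 in TIGIThigh, while KIT stood at 108 and 19.0. IL1R1 (-1.85), IL4I1 (-1.23) and GATA3 (-0.34) fell with KIT, and IL23R (-0.63) had an adjusted p of 0.010. Such cells and a difference between NK cells themselves, which was not tested, therefore both stay open.

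For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. For TIGIThigh against TIGITnegative, 1 split of 10, the real one, gave as many as 3349 genes (highest other 0), for TIGIThigh against TIGITlow 1 of 10 as many as 1003 (highest other 0) and for TIGITlow against TIGITnegative 1 of 10 as many as 1378 (highest other 1). For lists the counts were 1 of 10 splits with as many as 9 (highest other 7), 1 of 10 with as many as 15 (highest other 14) and 6 of 10 with as many as 12 (highest other 15). Mixed splits with at most 1 changed gene thus still called up to 7, 14 and 15 lists. The number of lists that camera called with the preset correlation therefore does not by itself mark a difference between fractions. Among 100 splits of the 9 libraries into 3 groups, 1, the real one, gave as many as 3236 genes (highest other 651). This argues against a random grouping of these libraries. If the replicates are technical, a chance difference between 3 samples would give the same result, so that is not excluded. For genes off the midpoint, 4 of 100 gave as many as 87, the real one included, which is under 0.05 (highest other 1162). All 3 larger splits had a whole fraction as their middle group, and splits without one there gave at most 47. Since the middle group was drawn at random, the share mostly counts how often a whole fraction was put there. It does not test whether TIGITlow lies off the midpoint.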
